A study of Lacticaseibacillus rhamnosus with 9 samples.

How the data were processed

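Total RNA was labelled with Cy3 and hybridised to NimbleGen arrays whose design text gives 7303 genes from 25 Lactobacillus genomes, whereas the deposited tables hold 48570 targets and 1 random control row. Per the labels, DNA was digested with DNase before labelling, each gene has several probe pairs with a technical redundancy on the array, and the cultures of a group were separate. The authors deposited 1 table per array with 1 intensity per target, and RMA is the only tool given in the submitters' processing notes, with no version. RMA corrects for background, normalizes arrays to a common distribution and summarises the probes of a target, so an overall shift of RNA levels between groups cannot be seen in these intensities. The parameters of that step are not given in the sources used here. The series' value table holds the same intensities as the array tables, with a largest difference of 0, on a linear scale and without centring. All 9 arrays lay on 1 slide and in 1 scan, so slide and scan were no batches. The number of arrays limits the precision.

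The intensities were taken to log2 without further normalization, and the control row was left out. Targets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in 1 fit of 3 group means over all 9 arrays, so that the groups share the estimate of the spread. The p-values are two-sided and adjusted by Benjamini-Hochberg over the 48570 targets, with a threshold of 0.05. Comparisons were packet against native, capsule against native and packet against capsule, with an F-test over the 3 groups. Groups, tests and most alternatives were fixed before the data were examined. The labels number the cultures 1 to 3 in each group, and the fit with that number as a block was an alternative.

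The fixed rule for naming took, where no table pairs targets with genes, the 2 highest and the 2 lowest fold changes per comparison among targets that passed the test and whose groups did not overlap. The reference gene table used here (ASM2847508v1, strain GG, 2830 genes) holds 0 of the array identifiers, so no target was given a gene name or an organism, and the gene lists fixed for cell surface, envelope and metabolism were not tested. Contig numbers, positions and strands are those in the identifiers, on an assembly whose name is not given in the sources used here.

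A background threshold was set per array as the 95th percentile of the targets outside the families contig, LGG and LC705. A run was defined as at least 5 neighbouring contig targets that passed the threshold in the same direction in both comparisons against native, and its level on an array as the median of its targets. Both definitions were made after the data had been seen. Runs were set against 100000 random orders of the contig targets with numpy 2.4.6 in Python 3.11.15. The correlation of the effects was set against 100 simulations of unchanged groups that share the native arrays. Other alternatives were the value table, quantile normalization and median centring of the log2 values, a filter on dim targets, only the 6 arrays compared, trend and robust settings of eBayes, array weights, stricter thresholds and leaving out each array in turn. A filter on control rows was not run because the tables hold 1 such row. A filter on species was not run because the tables give no species, and averaging of probes did not apply to 1 row per target. Standard errors in the tables were not used.

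The fit was tested on simulated data with the real native means and spreads and with independent noise. Among the 48570 targets, 200 contig targets with a native mean above 10 on the log2 scale were changed in packet against native. The fit recovered 42.4% of the changes of 1 log2 unit, 88.1% of those of 2 and 95.5% of those of 3, with 3 false calls among 154. These rates hold for bright targets and noise that is not shared between targets. Figures were drawn with matplotlib 3.10.9.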

Results

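RNA levels were measured on 9 single-colour NimbleGen arrays in Lcr35, a probiotic strain of Lacticaseibacillus rhamnosus, a lactic acid bacterium. Total RNA came from 3 separate overnight cultures in MRS medium, a rich medium for lactobacilli, of each of 3 preparations: the native strain and the packet and capsule formulations sold as restituo. The p-values rest on the spread between cultures. If the cultures of a preparation shared 1 product lot or stock, a difference of that lot or stock cannot be told apart from the preparation. The study asked how manufacturing affects the strain's surface properties. Each array gave 1 intensity for each of 48570 targets, whose identifiers fall into 26 families by their prefix. The median log2 intensity was 12.22 in the family contig, 10.83 in LGG and 11.05 in LC705, and between 4.67 and 5.33 in the other 23 families, near the 1 random control row, which lay at 4.67 to 4.71. A background threshold was set per array as the 95th percentile of the targets outside the 3 bright families, an intensity of 70.4 to 78.4. Between 77.0% and 92.9% of the targets of the 3 bright families lay above it on all 9 arrays. The 2762 contig targets carry positions on 54 numbered contigs, and their median level was between 12.13 and 12.31 on the log2 scale on every array. No file used here pairs the identifiers with gene names, so results are given by identifier and by position on a contig.

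The arrays of the native strain stood apart from those of both formulations. Across the contig targets, the mean pairwise correlation was 0.990 among the 3 native arrays, 0.989 among the 3 packet arrays and 0.956 among the 3 capsule arrays. It was 0.964 between packet and capsule arrays, 0.883 between packet and native arrays and 0.884 between capsule and native arrays. These correlations run across targets of the arrays, which are not independent replicates. The first principal component held 64.1% of the variance and separated the native arrays from the rest, whereas the second, with 28.3%, mainly set capsule replicate 1 apart. The SD of the difference between capsule replicate 1 and the mean of the other capsule arrays was 0.85 log2 units over the contig targets, against 0.20 to 0.69 for the corresponding value of the other 8 arrays.

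**Figure D1:**
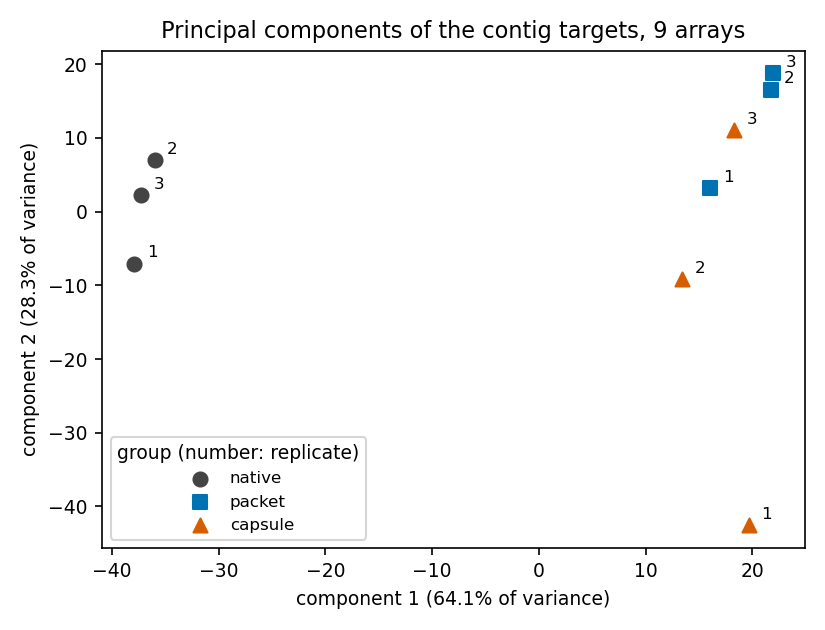
Principal components of the log2 intensities of the 2762 contig targets, with 1 point per array and its replicate number beside it. Component 1 (64.1% of the variance) separates the 3 native arrays from the 6 others, and capsule replicate 1 has the lowest value on component 2 (28.3%).

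The first comparison set the packet formulation against the native strain. In the packet cultures 732 targets were higher and 586 were lower than in the native cultures by limma's moderated test at an adjusted p of 0.05, of 48570 tested. Of these, 615 were higher and 399 lower by at least 2-fold. The contig family held 321 of the higher and 206 of the lower targets, so that 19.1% of its members changed. With the contig targets tested alone, and p adjusted over them, 1031 of them changed, 596 of them higher. The LGG family held 326 changed targets, the LC705 family 426 and all other families 39. By fitted fold change, the 2 highest increases were both on contig 6. The target contig00006_12565-12894 had a log2 intensity of 6.01 ± 0.83 in the native strain and 12.67 ± 0.72 in the packet cultures (SD, n = 3 each; limma adjusted p = 7.48e-06). Of its 3 native values, 1 lay above the background threshold. With values under the threshold raised to it, this target was an estimated 75.9-fold higher, which is not a lower bound. This target lies within contig00006_8241-13103_c on the opposite strand, which had a smaller log2 fold change of 4.34. The target contig00006_31178-31507_c went from 7.24 ± 0.52 to 13.19 ± 0.92, a log2 fold change of 5.94 with an SE of 0.49 (limma adjusted p = 2.53e-05). The 2 largest decreases by fitted fold change were contig00063_134356-134802, which went from 14.43 ± 0.13 to 8.65 ± 0.13, or 55.3-fold lower (limma adjusted p = 1.09e-07), and contig00004_83886-84821_c, which went from 13.34 ± 0.18 to 7.79 ± 0.12, or 46.9-fold lower (limma adjusted p = 5.63e-08). The log2 fold change of the latter, -5.55, was close to that of LC705_00392100700000385, -5.53, so their order is not resolved. All 3 packet values lay on one side of all 3 native values in 66.8% of the contig targets and 14.9% of all targets, against 10% by chance. The count of 1318 changed targets was 752 without packet replicate 2, 733 without packet replicate 3, 858 without native replicate 2 and 820 without native replicate 3. It was 2005 without capsule replicate 1, which enters through the shared estimate of the spread, and 2350 when only targets above the background threshold in every array of at least 1 group were tested. With only the 6 arrays compared, the count was 1787.

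The second comparison set the capsule formulation against the native strain. In the capsule cultures 710 targets were higher and 583 were lower (limma, adjusted p of 0.05), of which 581 and 421 differed by at least 2-fold. The contig family held 289 of the higher and 222 of the lower targets, the LGG family held 321 changed targets, the LC705 family 404 and all other families 57. With the contig targets tested alone, 1000 of them changed, 515 of them higher. The 2 increases with the highest fitted fold changes included LGG_00521110200000515, which went from 6.42 ± 0.10 in the native strain to 11.91 ± 0.33 in the capsule cultures (SD, n = 3 each), or 44.9-fold (limma adjusted p = 1.90e-07). The contig 6 target contig00006_12565-12894 reached 11.32 ± 0.72 (limma adjusted p = 5.01e-05), and 1 of its 3 native values lay above the background threshold. With values under the threshold raised to it, this target was an estimated 29.7-fold above the native strain. The opposite-strand target that spans contig00006_12565-12894, contig00006_8241-13103_c, had a log2 fold change of 3.31. The 2 decreases named were those of contig00004_82468-83874_c and LC705_00392100700000385. The first went from 12.18 ± 0.24 to 6.01 ± 0.94 (limma adjusted p = 3.38e-06), with 1 of 3 capsule values above the background threshold. The second went from 13.17 ± 0.19 to 7.08 ± 0.80 (limma adjusted p = 8.03e-07), with 2 of 3 capsule values above it. With values under the threshold raised to it, the decreases were an estimated 51.2-fold and 66.1-fold. The order within each of these 2 pairs is not resolved. Groups did not overlap in 47.4% of the contig targets and 14.99% of all targets, against 10% by chance. The count of 1293 changed targets was 838 without native replicate 2, 845 without native replicate 3 and 2376 with the filter on background. It was 1419 without capsule replicate 1, the array that stood apart.

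Many targets changed from the native strain in the same direction in both formulations. Of the targets called in each comparison, 531 were higher in both and 449 were lower in both, and 0 were called in opposite directions. Independent lists of these sizes would share 10.7 higher and 7.03 lower targets if drawn from all 48570. Within the 8244 targets of the contig, LGG and LC705 families, which hold most calls, 506 were higher and 445 lower in both, against 56.9 and 39.8 for independent lists. The log2 fold changes correlated across all targets with r = 0.761 and across the contig targets with r = 0.896. Unchanged groups simulated against the same native arrays gave a mean r of 0.50 and 0.498. The covariance was 0.158 across all targets, against 0.0396 in the simulations, and 1.05 across contig targets, against 0.0484. The share of targets with the same sign was 66.8% over all targets, against 66.7% in the simulations, and 82.9% over contig targets, against 66.7%. Both comparisons share the 3 native arrays, too few to split, so part of the overlap may come from them. Targets are not independent replicates. The design text gives 7303 genes for the 48570 targets, so 1 gene may have several targets, also in different families. These counts and expected overlaps are therefore of targets, not of genes.

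**Figure D2:**
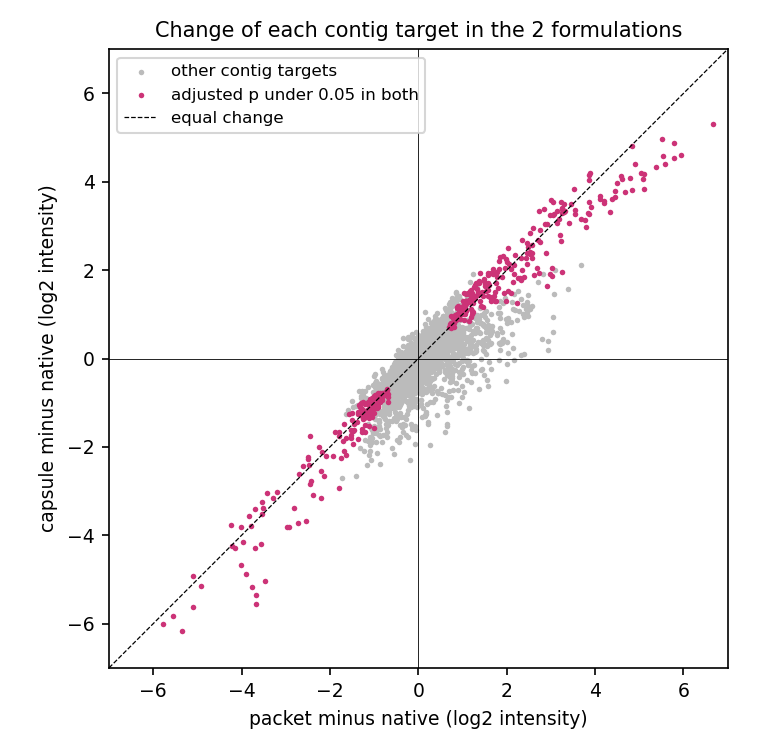
Log2 fold change of each of the 2762 contig targets in packet against native (horizontal) and capsule against native (vertical), with the dashed line marking equal change. The 400 targets in colour passed an adjusted p of 0.05 in both comparisons and lie in the lower left or upper right of the plot (r = 0.896 over all contig targets).

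Part of the changed contig targets lay in blocks. Of the 400 contig targets changed in both comparisons, 233 were higher and 167 lower, and 117 of them formed 10 runs of at least 5 neighbouring targets that moved the same way. Across 100000 random orders of the targets, the mean number of such runs was 0.0115 and the highest was 2 (one-sided permutation p = 1e-05, the smallest these shuffles can give). Random orders also part targets that overlap, as some in the runs do, so this p does not separate grouping of genes from overlap. Neighbouring targets that do not overlap had similar changes, with r = 0.652 for packet and 0.628 for capsule over 1894 pairs. The search for runs was chosen after the data had been seen, and the number of runs was 18 without capsule replicate 1, 18 with the filter on background and 22 with the contig targets tested alone. Overlapping targets on opposite strands also moved together, with r = 0.917 for packet over 408 pairs, so the strand of origin is not resolved by these values.

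The longest run was higher in both formulations. It held 46 targets, some of them overlapping, between positions 816 and 35674 of contig 6, with 40 on one strand. Its median log2 intensity was 10.32 ± 0.02 in the native strain, 14.52 ± 0.41 in packet and 13.95 ± 0.39 in capsule (SD, n = 3 each), which is 18.4-fold and 12.4-fold above native. On contig 6 as a whole, 47 of 49 targets passed the test as higher in both formulations and 1 as lower in both, and the remaining target had fold changes above 0 in both without passing in both. On contig 16, a run of 6 targets from 23315 to 27324 was 11.4-fold higher in packet and 8.01-fold higher in capsule. On contig 28, a run of 7 targets from 10922 to 14869 was 9.13-fold and 9.96-fold higher, and a run of 5 targets from 73807 to 77658 was 9.37-fold and 6.28-fold higher. A run of 6 targets from 105372 to 110096 of contig 40 was 6.35-fold and 6.02-fold higher. The smallest increases were those of 5 targets from 60135 to 65366 of contig 5, at 2.15-fold and 2.37-fold, and of 6 targets from 85790 to 89456 of contig 40, at 1.97-fold and 2.20-fold.

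The remaining 3 runs were lower in both formulations. On contig 63, 11 targets from 130110 to 139204, 10 of them on one strand, had a median of 14.74 ± 0.03 in the native strain, 10.54 ± 0.12 in packet and 10.31 ± 0.17 in capsule (SD, n = 3 each), or 18.4-fold and 21.6-fold lower. On contig 28, 7 targets from 49215 to 53338 had a median of 15.44 ± 0.04 in the native strain, 11.92 ± 0.27 in packet and 12.15 ± 0.33 in capsule, or 11.4-fold and 9.78-fold lower. On contig 40, 18 targets from 60110 to 70693 went from 12.19 ± 0.10 in the native strain to 10.03 ± 0.21 in packet and 10.18 ± 0.20 in capsule.

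**Figure D3:**
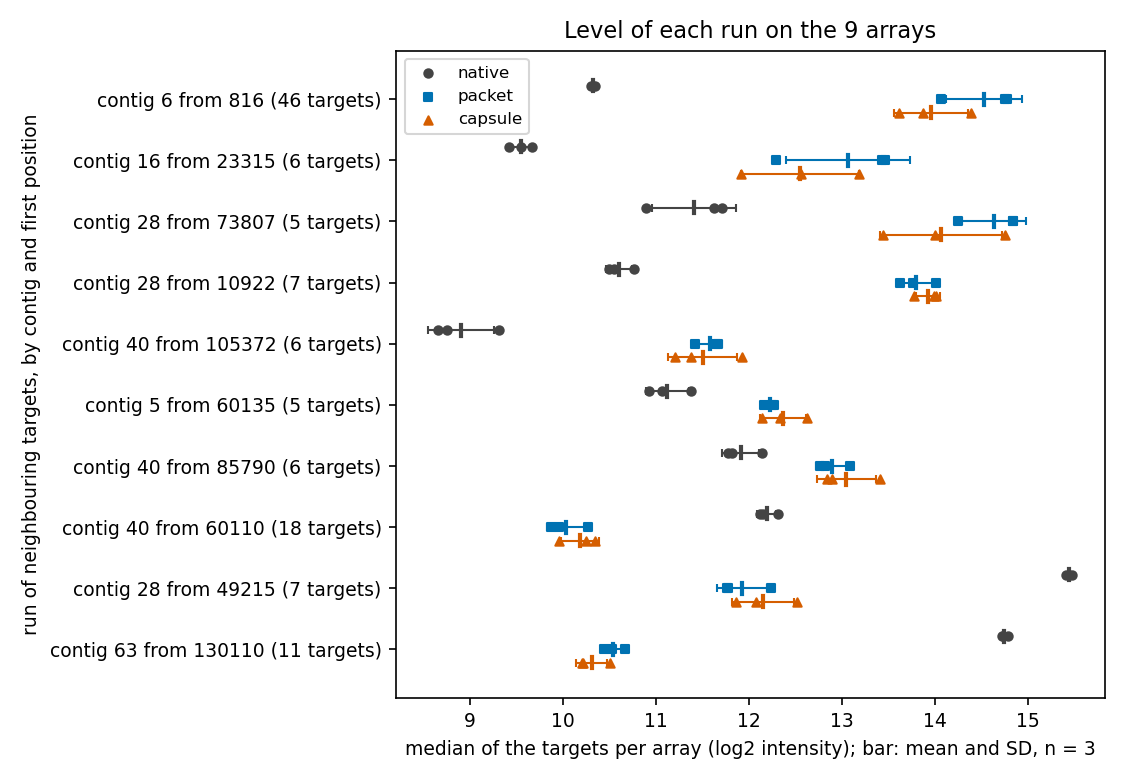
Median log2 intensity of each of the 10 runs on each of the 9 arrays (points), with the group mean and SD (bars, n = 3). The 7 runs at the top were higher and the 3 at the bottom lower in both formulations, as each of their targets had to be to enter a run.

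**Figure D4:**
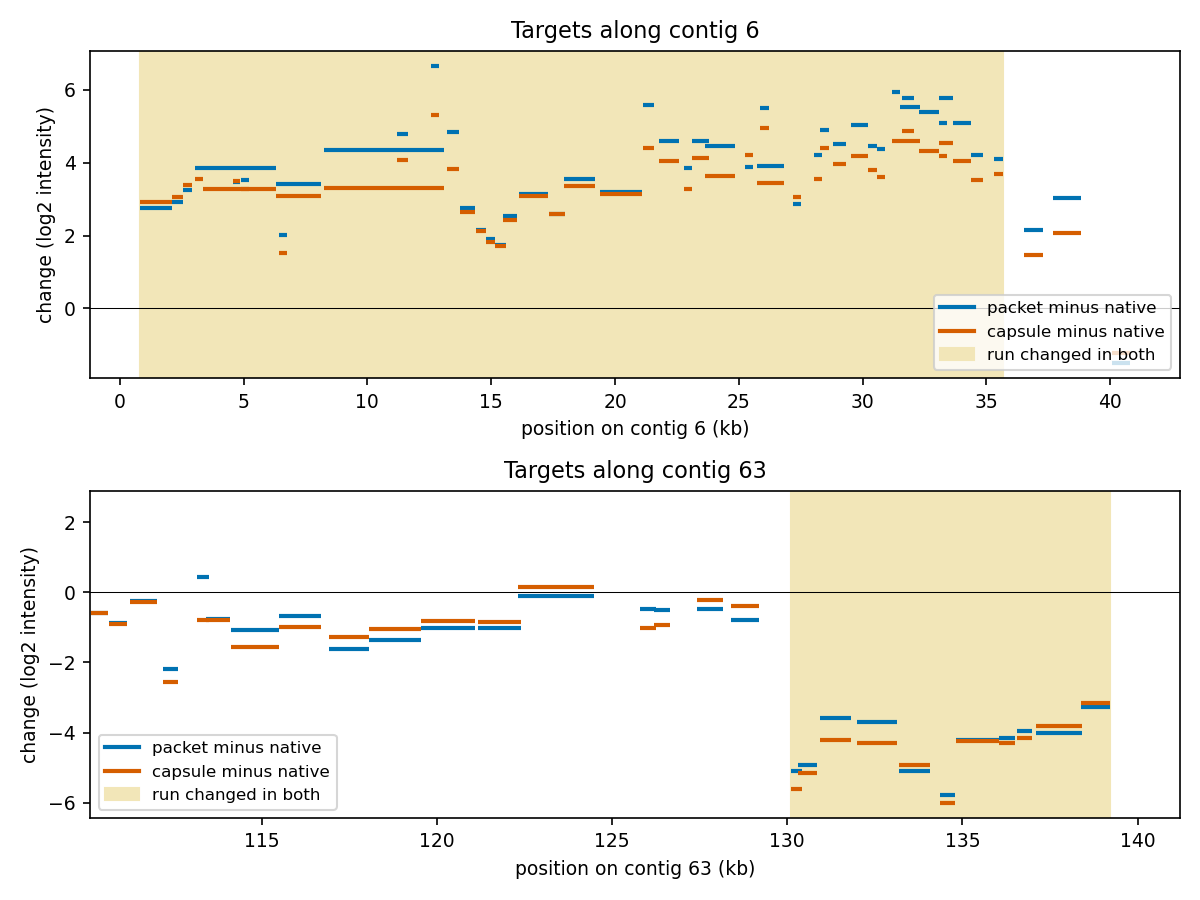
Log2 fold change against native of each target along contig 6 (top) and the end of contig 63 (bottom), where each bar spans a target's positions in kilobases and the shaded span is the run of changed neighbours. The run of 46 targets on contig 6 lies above 0 and the run of 11 targets on contig 63 lies below 0 in packet and capsule.

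The third comparison set packet against capsule. By limma 0 targets passed an adjusted p of 0.05, and the smallest adjusted p was 0.894. At an unadjusted p under 0.05 there were 2450 targets, or 5.04% of those tested. The 95% interval of the difference reached a median of 0.47 log2 units to either side over the contig targets, and in 71.9% of them it lay within 2-fold. The estimated difference exceeded 2-fold in 201 contig targets. Over the 10 runs, the difference of the group means, packet minus capsule, was between -0.22 and 0.58 log2 units, above 0 in 5 runs and below 0 in 5. Groups did not overlap in 9.63% of the contig targets and 10.3% of all targets, where chance gives 10%. With 3 arrays per group, an exact permutation test of a single value cannot go below p = 0.1. The count was 2 without packet replicate 3.

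Across the 3 preparations together, limma's F-test called 1273 targets, of which 507 were contig targets, and 99.3% of the 1273 were also called in packet or capsule against native. With the contig targets tested alone, 968 of them were called. The count was 837 without native replicate 1, 730 without native replicate 2 and 726 without native replicate 3. It was 1918 with weighted arrays and 2268 with the filter on background.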

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

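The background filter, the contig targets alone and the runs were chosen after the data had been seen. In each fit that tested them, the 8 named changes kept their direction and stayed past an adjusted p of 0.05, and with quantile normalization or median centring the median changes of the 10 runs moved by less than the larger SD of the 2 groups compared. Counts moved more. With the filter on background, the changed targets numbered 2350 in packet against native, 2376 in capsule against native and 2268 among the 3 groups, with 18 runs; fewer targets were then tested. With contig targets alone, 1031, 1000 and 968 of them were called, against 527, 511 and 507 of them among all targets. The adjustment of p and the spread that limma shares across targets then both rest on fewer targets. There were 22 runs, the correlation of the effects was 0.896, and that of arrays between groups was 0.910, against 0.975 over all targets. At an adjusted p of 0.01 the counts were 738, 770 and 740. With array weights 1918 targets differed among the 3 groups, and the cause was not tested. With only the 6 arrays compared, 1787 targets changed in packet against native and 875 in capsule against native. Leaving out 1 array at a time gave 733 to 2005 targets for packet against native, 838 to 1419 for capsule against native, 0 to 2 for packet against capsule, 726 to 1678 among the 3 groups, and 7 to 18 runs; most of these fits have fewer arrays in an arm, and without capsule replicate 1 the packet and native estimates are the same, so the rise to 2005 comes from the shared estimate of the spread, and the cause of the other rises was not tested. The 2 targets called without packet replicate 3 belong to the families LDBND and LSL. Same-numbered arrays deviated together with r between -0.185 and 0.292 over all targets, above 0.1 in 6 of 9 pairs. Over the contig targets r was between -0.390 and 0.713, above 0.1 in 7 of 9 pairs, and in native with packet it was 0.544, 0.326 and 0.210. Since not every pair passed 0.1 over all targets, the numbers were not taken to pair the cultures, but over the contig targets native and packet arrays would meet that limit; 6 of 9 arrays were closest to an array of their own number in another group. The replicate block gave 1536, 1534 and 0 changed targets in the 3 comparisons, 1538 among the groups and 11 runs. Signal near background limits the dim targets, for which a fall cannot be seen.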

Other observations

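Among the tests below, those on missing DNA, on genomic DNA, on scaling and on single spots were chosen after the result was seen. Few targets outside the families contig, LGG and LC705 changed, and they were concentrated in 3 families. LCABL held 19 of the 39 in packet against native, LSEI 13 and LCAZH 4, and in capsule against native these families held 22, 17 and 4 of 57. They are also the families with the largest shares above background on all 9 arrays after those 3, at 5.03%, 3.85% and 3.93%. Of the 64 overlapping pairs on opposite strands with at least 1 target changed in both comparisons, 64 moved the same way in packet against native.

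The block on contig 6 was higher in packet and capsule. Absence of the block from all native cells is argued against, since 95.7% of its targets lay above background on all 3 native arrays. Loss from a part of the native cells could leave signal above background, so it stays open. Cells of an organism behind the families outside contig, LGG and LC705 are argued against too, since none of those families had a median change above 0.0325. Cells of another strain behind the 3 bright families were not tested. Genomic DNA could raise dim targets, and the other contig targets with a mean of the 2 groups below 10 had a median change of 0.51 in packet (512 targets) and 0.07 in capsule (533 targets), so a part played by DNA stays open; as the source of the whole rise it is argued against, since of the 542 other contig targets with a native mean below 10, a choice that favours rises, 15.7% in packet and 9.96% in capsule rose by at least the smallest change in the block. A change in copy number of the block and an effect of the formulation on its transcription stay open, as neither was tested.

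The run on contig 63 was lower in packet and capsule. The median change of all contig targets was 0.06 in packet and -0.012 in capsule, so the run fell relative to the median contig target. Normalization to a common distribution tends to hold this median steady, so whether all contig targets shifted cannot be judged. As the source of the fall of the run, a shift common to all contig targets is argued against. The median of the run changed by -4.20 in packet and -4.44 in capsule, far from the median contig target. Absence of the run from all formulation cells is argued against, since 100% of its targets lay above background on all 6 packet and capsule arrays. Loss from a part of the cells could leave signal above background, so it stays open, as does a change in copy number. An effect of the formulation also stays open as a hypothesis and was not tested further.

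Capsule replicate 1 stood apart, with 517 contig targets lower and 121 higher by at least 2-fold than the mean of the other capsule arrays, and 11 runs of at least 5 neighbouring targets, each of them lower. Scaling with signal strength is argued against as the main source, since a loess fit on mean signal removed 9.84% of the variance. Noise of single spots is argued against by a correlation of 0.306 between neighbouring targets that do not overlap, above the highest of 1000 shuffled orders, 0.0847. The deviation of capsule replicate 1 had a correlation of -0.0163 with the log2 length of the targets. Loss of long RNA stays open, since the targets do not give the length of transcripts. A difference of that culture may be the source; no biological explanation was tested.

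Among 100 splits of the 9 arrays into 3 groups of 3, 2 gave as many differing targets as the real one with 1273, itself included. For a free exchange of the 9 arrays this share is under 0.05, but the count does not single out the real split. Both of these splits keep the native arrays together, so the share bears on native against the rest and not on packet against capsule. The highest other split gave 1737. It set packet replicate 1 with capsule replicates 1 and 2, against packet replicates 2 and 3 with capsule replicate 3. The first of these sets lay at 3.17, -42.5 and -9.15 on component 2 of the contig targets and the second at 16.5, 18.8 and 11.1, whereas a direct comparison of the 2 sets gave 0 changed targets. The split keeps packet and capsule arrays of numbers 1 and 3 together, whose deviations correlated with r = 0.428 and 0.713 over contig targets, and parts those of number 2, with r = -0.390. With the number as a block, 1538 targets differed among the groups. The 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 1318 targets in packet against native and 1293 in capsule against native, with 0 as the highest of the others, and in packet against capsule 10 of 10 splits gave 0.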
